A study of Homo sapiens with 3 samples.

How the data were processed

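ChIP-seq against the AM tag was done in HEK293T cells, per the labels' protocols: cells were fixed with formaldehyde, chromatin was cut with micrococcal nuclease and sonication, and libraries were sequenced as read pairs on an Illumina NovaSeq. The submitters' processing notes name the hg38 build, Bowtie2 2.4.2, MACS2 2.1.1.20160309.6, ChIPseeker 1.18.0, deepTools 3.3.2.0.0 and 3.5.1.0.0, and HOMER 4.10, without a role or order for any of them. The labels gave 3 groups of 1 library. The file used holds annotated peaks and carries the genotype name of the wild-type library, while the series record ties it to no sample, so its assignment rests on that name. Lists for the vector and R750W libraries were not analysed here. With 1 list there was no comparison between groups, and the signal of the tag antibody in vector cells was not examined here.

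The deposited table has no header, so its columns were identified from their values. The deposited fold enrichment of a peak is a ratio of fragments to local background and ran from 1.45 to 669. The deposited −log10 p-value and −log10 q-value are those of the authors' peak caller, and the lowest −log10 q was 2.00. The deposited score was the whole part of 10 times the −log10 q in all 3465 lines. Fold, score and q are the authors' own values for each peak and were used to describe, rank and filter peaks within this list. The table assigns each peak to an Ensembl gene by nearest gene start and gives its place relative to that gene. Of the lines, 3 repeat a peak with another gene, leaving 3462 peaks, of which 43 lie on sequence outside the assembled chromosomes and have no gene. Columns of values tied to no group numbered 0.

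Fragments behind each peak, taken as the count at its highest point, were worked out from the deposited fold and p-value. For each peak a single whole number of fragments and background were found for which (fragments + 1)/(background + 1) gave the fold and the Poisson tail gave the −log10 p, within 0.001, or a share of 1e-05 above 1000. This held for all 3462 peaks, and for 100% of 500 simulated peaks. The simulation covered neither the highest backgrounds nor the fold and fragment counts of the highest peaks inside MECOM. The lowest background, 1.70 fragments, occurred at 422 peaks. Above it, 54.3% of backgrounds were whole multiples of 0.593 fragments within 0.002, against 0.62% for random values, so the background was taken to be scaled from a second library, whose identity is not given in the sources used here. Total reads per library are not given in the sources used here. Intervals on fold are exact 95% Poisson intervals of the fragments with the background held fixed.

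Gene spans and types came from NCBI RefSeq on GRCh38.p14, without strand or exons. Of 2286 symbols in the list, 2256 matched. Of 2202 genes compared, 75.9% had both ends within 1000 bp and 100% overlapped on the same chromosome. Random intervals kept peak widths and chromosomes (100 draws). The height test permuted classes 100000 times, two-sided. The deposited table has no promoter class, so peaks that span a gene start or cover the whole gene took its place. Gene lists were tested by the number of members assigned a peak against 10000 random lists from the same 10 length classes, a permutation of list membership within those classes, two-sided, with Benjamini-Hochberg adjustment over the 15 lists, and the smallest raw p is 0.0002. In simulation, random lists passed a raw p of 0.05, without adjustment, in 0 to 1% of draws. Lists of 30, 40 and 80 genes with a 3-fold share passed in 82, 88 and 96%. With a 2-fold share they passed in 28, 39 and 68%. The adjusted threshold is stricter, so lists short of it may still hold a moderate excess. Peaks were simulated independently for each gene, so these rates do not cover lists of clustered genes.

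Tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took MECOM and GATA2, the 15 highest peaks outside MECOM, the 10 highest peaks across a gene start, the 5 genes with most peaks, and up to 4 members of each list by highest fold. Some members that the rule takes are not reported here. Where a highest peak's assigned gene had no symbol, the RefSeq gene around or nearest to it was named in its place. Planned tests of 15 sequence motifs and of overlap with MECOM exons were not run, because no genome sequence or exon positions were used here; the MECOM gene span took the place of its exons. Alternatives were a q of at most 1e-05, the higher peaks by fold, merged neighbours, autosomes and a start defined by distance. Others were −log10 q in place of fold, peaks across a start only, matching on gene territory, and Fisher's exact test. A gene's territory reached midway to the middle of each neighbouring gene and so included the gene itself. A widened gene span, removal of peak-dense windows and removal of the 3 high MECOM peaks were added later. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.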

Results

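Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in HEK293T cells, a human embryonic kidney line, to locate DNA bound by MECOM. MECOM is a zinc finger transcription factor, also known as EVI1, whose raised expression marks a group of myeloid leukaemias. The protein carried an AM tag, a short peptide recognised by the antibody used for the precipitation. The 3 libraries came from cells given an empty vector, wild-type MECOM or the R750W form of MECOM, with 1 library in each group. The series concerns MECOM in leukaemia and mast cell differentiation and its competition with GATA2. The annotated peak list examined here is that of the wild-type library, and the lists of the other 2 groups were not analysed here. No difference between groups was therefore tested, and no peak value has a replicate. The list held 3462 peaks with a median width of 414 bp. A median of 18 fragments lay at a peak, with quartiles of 15 and 22, against a median expected background of 2.92 fragments. At that depth a peak's fold enrichment has a 95% exact Poisson interval from 2.98 to 7.52, so most peaks could not be ranked against each other. Such intervals cover counting error in the precipitated library only.

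The 3 highest peaks of the list lay inside MECOM itself, which spans chromosome 3 from 169083507 to 169663712 in the hg38 build. The highest, from 169115354 to 169116752, had a fold enrichment of 669 (95% interval 652 to 688) with 5397 fragments over a background of 7.06. A peak from 169127807 to 169128084 reached 378-fold with 1048 fragments, and one from 169089974 to 169090264 reached 360-fold with 1425 fragments. These 3 peaks covered 1968 bp, or 0.339% of the gene. They were 17 to 31.7 times as high as the highest peak elsewhere, which reached 21.1-fold. The other 2 peaks inside MECOM were of ordinary height, at 7.40-fold (5.00 to 10.6) and 3.73-fold (2.23 to 5.92). The deposited annotation named the nearest gene start and so gave none of the 5 peaks to MECOM. Whether the peaks lay on exons or introns was not determined, since exon positions were not used here. At the 3 highest peaks, DNA of the introduced MECOM construct and binding within MECOM therefore cannot be told apart.

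**Figure D1:**
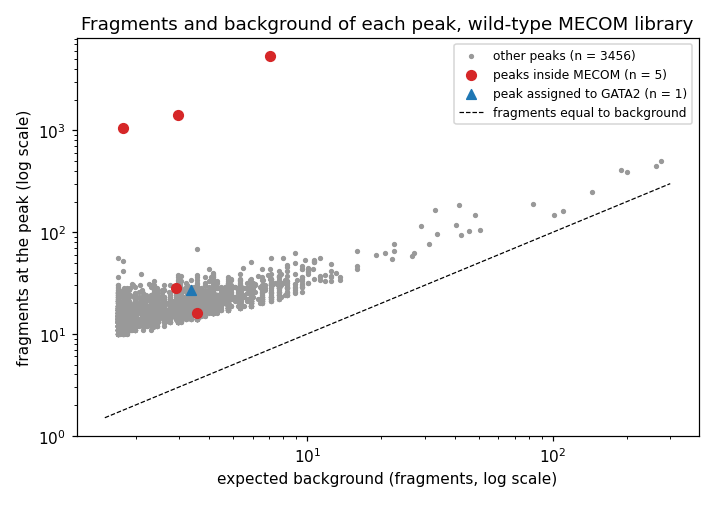
Fragments at each peak of the wild-type MECOM library (vertical axis, log scale) against the expected background in fragments (horizontal axis, log scale), with 1 point per peak. All 5 peaks inside MECOM are red. The 3 highest hold 1048 to 5397 fragments and stand apart from all others. The other 2 and the GATA2 peak (blue triangle) lie among the remaining peaks.

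GATA2, a transcription factor of blood stem cells and mast cells and the proposed competitor of MECOM, had a single assigned peak. It lay on chromosome 3 from 128496004 to 128496437, 2819 bp upstream of the annotated gene start. Its enrichment was 6.40-fold (4.29 to 9.20), from 27 fragments over a background of 3.38. MITF, a regulator of mast cells and melanocytes, had a weaker peak at its gene start (2.89-fold, 1.80 to 4.43). These were the 2 of 36 mast cell genes assigned a peak, against 3.20 expected for genes of matched length (adjusted permutation p = 0.791). ETV6, a transcriptional repressor rearranged in leukaemia, had the highest peak among the haematopoietic transcription factors, at −972 bp from its start (8.59-fold, 5.88 to 12.1).

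Outside MECOM, 23 of the 3457 peaks reached an enrichment of 10 or more. The highest lay within CDKAL1, a gene for a tRNA-modifying enzyme, on chromosome 6 from 20835230 to 20836011 (21.1-fold, 16.1 to 27.3, 56 fragments). A peak within ADGRL2, an adhesion receptor gene, lay on chromosome 1 from 81874361 to 81874978 (19.1-fold, 14.3 to 24.9). A peak across the start of SERINC1 on chromosome 6 reached 15.5-fold (11.3 to 20.8). A peak within UCHL3, a deubiquitinase gene, on chromosome 13 reached 15.4-fold with 69 fragments. The peak at ZNF484 reached 13.7-fold, and that across the start of TAF13, a subunit gene of the general transcription factor TFIID, 12.9-fold. Enrichment of 10.4 to 11.5 was found 11587 bp from VIM, within ERC1, within VAV1 (a peak assigned to ADGRE1) and within the receptor tyrosine kinase gene EPHA3. Other peaks in this range lay 84 bp upstream of MBD4 (within IFT122), 4164 bp upstream of GABRR3, and at HINFP, WDFY3 and ZNF264. Successive intervals in this order overlapped, so neighbours in it were not ranked. The interval of CDKAL1 lay wholly above those of EPHA3, MBD4, GABRR3, HINFP, VAV1, WDFY3 and ZNF264. The peaks of CDKAL1, ZNF484, ERC1, EPHA3, GABRR3, VAV1 and WDFY3 and that near VIM sat at the lowest background of the list, 1.70 fragments. The median background was 2.92. High fold thus came partly with low background, and the intervals leave out error in the background. Of the 3457 peaks outside MECOM, 185 had an interval wholly above the median enrichment of 4.82. Each interval was taken alone, without adjustment for the number of peaks. Counting error alone would put some peaks wholly above the median, so the 185 are not all shown to be stronger.

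Among peaks that spanned a gene start, the 10 highest included those of SERINC1, TAF13, HINFP and WDFY3, of PROS1, the gene of the anticoagulant protein S (10.0-fold), and of ZSCAN23 (9.74-fold). The others belonged to annotated genes without a symbol. They lay on chromosome 1 from 119327236 to 119327985 (10.1-fold), on chromosome 17 from 27332732 to 27333357 (9.72-fold), inside ZSCAN26 (9.64-fold) and 458 bp from GLDC (9.33-fold). No gene was assigned more than 4 peaks. Of the 7 genes with 4 peaks none had a symbol, and ENSG00000241383 owed its 4 peaks to the MECOM locus. A further 27 genes had 3 peaks each. Of those with a symbol, the examples with the highest best peak, named after their values were seen, were CXCR4 (6.82-fold), TNFRSF1A (6.66) and JADE2 (6.37).

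Peaks gathered around gene starts. Of the 3419 peaks with an annotated gene, 1904 began within 1000 bp of its start (55.7%, exact 95% interval 54.0 to 57.4) and 2770 within 10000 bp (81.0%). By the annotation's own classes, 1382 peaks lay inside the gene (40.4%, 38.8 to 42.1), 952 upstream (27.8%) and 390 downstream (11.4%). A further 662 spanned the gene start (19.4%), 20 spanned its end and 13 covered the whole gene, which put 675 peaks (19.7%, 18.4 to 21.1) across a start. Within 1000 bp of either end of a protein-coding gene lay 1879 peaks (55.0%). The mean over 100 draws of random intervals of the same widths was 116 (3.38%), and no draw exceeded 137. Protein-coding genes overall overlapped 2353 peaks, 1.59 times the random mean, and long non-coding RNA genes 610 peaks, 1.20 times the random mean.

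**Figure D2:**
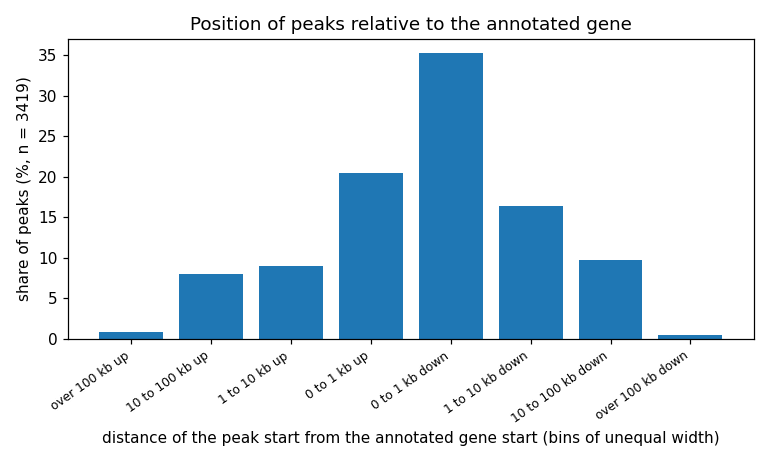
Share of the 3419 annotated peaks (vertical axis, %) by the distance of the peak start from the annotated gene start (horizontal axis, bins of unequal width). The bins within 1 kb on either side hold 20.4% and 35.3% of peaks; distances run from the peak's lower coordinate, which moves peaks at genes on the reverse strand downstream.

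Peaks across gene starts did not differ detectably from the rest in fold enrichment. Their mean log2 enrichment was 2.27 ± 0.39 (SD, n = 675) against 2.28 ± 0.43 (SD, n = 2744) for other peaks, a difference of −0.01 (two-sided permutation test, p = 0.444). The other peaks included many that began within 1000 bp of a start without spanning it. With a start defined as a distance within 1000 bp, the 1904 near peaks were lower by a small margin, at 2.25 against 2.31 (difference −0.06, permutation p = 2e-05, the second smallest the resampling can give). Median background was 2.96 fragments at the near peaks and 2.37 at peaks over 10000 bp from a start, with medians of 18 and 17 fragments. By −log10 q without the 3 high MECOM peaks, a setting added after the data were seen, peaks across a start were higher, at 6.48 against 6.07 (permutation p = 0.0142). Peaks are not replicates, so these tests describe this list alone.

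Of 20037 protein-coding genes, 1996 (9.96%) were assigned a peak, and 5 of the 15 gene lists differed from length-matched random lists at an adjusted p below 0.05. Replication-dependent histone genes had peaks at 14 of 69 members against 2.79 expected (adjusted permutation p = 0.0015), among them H2BC17 (7.31-fold), H2AC15 (7.12), H2BC5 (7.05) and H4C11 (7.04). The highest peaks of these 14 genes all lay on chromosome 6 from 25 to 30 Mb or chromosome 1 from 145 to 150 and 225 to 230 Mb. Those windows held 52, 33 and 25 peaks, and without peak-dense windows the list could not be tested. HOX genes, which pattern the body axis, had peaks at 9 of 39 against 2.29 expected (adjusted permutation p = 0.003), led by HOXB13 (5.84-fold), HOXD3 (5.4), HOXD4 (4.83) and HOXC5 (4.51). Genes of ERK feedback and the immediate early response had peaks at 8 of 33 against 2.60 expected (adjusted permutation p = 0.0232). They included SPRED1 (5.93-fold), a negative regulator of RAS signalling, EGR1 (5.49), MYC (4.98) and SPRED2 (4.98). Haematopoietic stem cell and leukaemia transcription factors had peaks at 10 of 34 against 4.35 expected (adjusted permutation p = 0.0474), among them MYC (4.98-fold) beside ETV6 and GATA2. Olfactory receptor genes had fewer peaks than random lists, at 1 of 390 (OR2V2) against 21.5 expected (adjusted permutation p = 0.0015). The raw p of the histone and olfactory lists, 0.0002, was the smallest the random lists can give.

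The haematopoietic call was lost in 6 of its 9 alternative settings, at adjusted p from 0.0678 to 1, the HOX call in 4 (0.114 to 0.662), the ERK call in 3 (0.099 to 0.737) and the olfactory call in 1 (0.114). The ratio of observed to expected members also moved with the setting, from 5.02 to between 2.04 (no length matching) and 8.40 (peaks across a start only) for histone genes, and from 3.93 to between 2.32 and 6.08 for HOX genes under the same settings. The haematopoietic ratio, 2.30, was 1.89 to 2.27 in 5 of the settings that lost its call and 0.954 with peaks across a start only. The ERK ratio, 3.08, was 3.71, 3.23 and 2.03 in the settings that lost its call. Histone, HOX and olfactory receptor genes lie in clusters, and neighbouring genes are not independent draws, so their p-values are too small by an unknown amount.

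The other 10 lists did not pass. TGF-beta and BMP pathway genes had peaks at 10 of 42 members against 4.82 expected (adjusted permutation p = 0.0915), with SMAD7 at 6.68-fold, BMPR1B at 6.67, SMAD2 at 5.34 and SMURF1 at 5.04. Kidney development genes counted 8 of 38 against 3.74 (adjusted permutation p = 0.124), with TFAP2A at 5.86-fold, PAX8 at 5.04, SALL1 at 4.76 and TBX18 at 4.72. Cell cycle and apoptosis regulators counted 8 of 40 against 3.83 (adjusted permutation p = 0.127), with BBC3, which encodes the pro-apoptotic protein PUMA, at 6.14-fold, BCL2L11 at 5.05, CCND1 at 4.61 and CCND3 at 4.38. Corepressor and chromatin partner genes counted 7 of 40 against 4.92, led by RCOR1 (7.41-fold), CHD4 (5.93), KAT2B (4.63) and EZH2 (4.34). PRDM family genes, to which MECOM belongs, counted 4 of 19 against 2.38, with PRDM7 at 6.23-fold, PRDM2 at 6.03, PRDM13 at 5.19 and ZNF408 at 5.04. AP-1 family genes counted 4 of 26 against 2.28, among them FOS at 6.54-fold, BATF3 at 5.84 and JUN at 4.66. Each of these last 3 lists had an adjusted p of 0.536. MECOM was not counted in its family because the table assigned it no peak. With the gene span widened by 1000 bp, a setting added after the data were seen, the family counted 7 of 19 against 3.34 (adjusted permutation p = 0.136). Ribosomal protein genes counted 5 of 86 against 5.49 (adjusted permutation p = 1), with RPL10L at 6.30-fold, RPS3 at 5.93, RPL10 at 5.58 and RPS29 at 5.54. Myeloid differentiation genes counted 1 of 30 against 2.31 (VCAN, 5.36-fold; adjusted permutation p = 0.728). No erythroid or megakaryocyte gene of 30 was assigned a peak, against 2.41 expected (adjusted permutation p = 0.269). With the widened span, 2 of these 30 genes held a peak, against 3.19 expected (adjusted permutation p = 0.847). The kidney ratio of observed to expected, 2.14, was 1.06 among the higher peaks, 1.36 with the widened span and 3.28 with peaks across a start only. The cell cycle ratio, 2.09, was 1.02 among the higher peaks and 1.06 with peaks across a start only. The PRDM ratio, 1.68, ran from 1.64 to 3.48 over the alternative settings, and the AP-1 ratio, 1.76, from 0.971 to 3.19. Neither list passed the threshold in any of them. Some of the named peaks lay outside the gene and over 10000 bp from its start, those of SMAD7 (48820 bp), PAX8 (−45875 bp), RPL10L (21334 bp), RPS3 (−15099 bp) and BBC3 (−10776 bp).

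**Figure D3:**
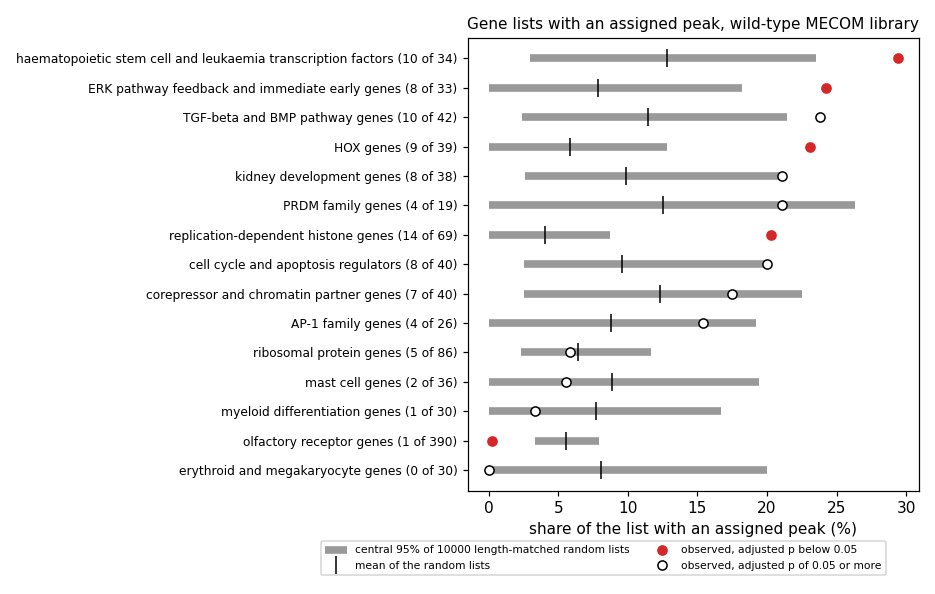
Share of each list with an assigned peak (points, horizontal axis, %) beside the mean (tick) and central 95% (bar) of 10000 random lists matched on gene length, for 15 lists. Red points mark the 5 lists with an adjusted p below 0.05; olfactory receptor genes, at 1 of 390, are the one red point below its bar.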

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

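The settings that left out windows of 5 Mb with 15 or more peaks, took the gene span widened by 1000 bp or left out the 3 high MECOM peaks were chosen after the data were seen, as was the count of MECOM peaks over 100-fold, which replaced the planned overlap with exons; that count was 3 in each of the 5 other settings run. The share of peaks across a gene start was 19.7%; it was 21.8% at a q of at most 1e-05 and 55.7% by distance, and stayed inside its interval in the other 4 settings. The height difference of −0.01 turned to 0.01 (0.0098) among the higher peaks by fold and passed the threshold by distance at −0.06 (−0.0619); the cause was not tested. It stayed negative and short of the threshold in the other 6 settings, of which that with −log10 q (−6.46) rested on the 3 high MECOM peaks: without them it was 0.405 (permutation p = 0.0142). The number of lists past the threshold was 5 in the main setting. It was 3 at the stricter q, 2 among the higher peaks, 2 without the dense windows and 1 with peaks across a start only. It was 3 with matching on gene territory, 4 with the widened span, 6 by Fisher's exact test and 5 with merged neighbours and on autosomes. The first 4 settings keep fewer peaks, and the histone list had too few genes left to be tested without the dense windows. The ratio of observed to expected changed side for ribosomal protein genes (1.29 at the stricter q, 1.37 among the higher peaks, 1.16 without dense windows, 1.63 across a start) and for corepressor genes (0.813 among the higher peaks, 0 across a start). With peaks across a start only it also changed side for mast cell genes (1.31), haematopoietic factors (0.954) and TGF-beta genes (0), and with the widened span for AP-1 genes (0.971). None of these ratios passed the threshold. Of the other list values, 110 kept their direction and side of the threshold, 13 fell short of it and 1 passed it (TGF-beta genes by Fisher's exact test, adjusted p = 0.0302). Motif tests and exon overlap, with their alternatives, were not run. No paired analysis was possible because each group has 1 library and a single list was used. A median of 18 fragments per peak limits the ranking of peaks.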

Other observations

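The gene lists, window tests, transfer RNA counts and explanations in this part were all chosen after the peaks had been seen, except the planned test of ribosomal protein genes. Transfer RNA genes carried more peaks than random placement gave. Of the peaks, 28 overlapped a transfer RNA gene against a mean of 0.55 and a maximum of 3 in 100 draws, and 69 lay within 1000 bp of an end of one against a mean of 1.55. Their enrichment ran from 2.18 to 7.42-fold with a median of 4.79, close to the median of 4.82 of all peaks. Of the 28, 13 lay on chromosome 6 between 25 and 30 Mb, a window with 52 peaks, and 9 on chromosome 1.

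Among 8 further gene families, homeobox genes outside the HOX clusters had peaks at 22 of 75 members against 7.09 expected from length-matched lists (adjusted permutation p = 0.0016), led by MEIS3 (8.13-fold), ZFHX4 (5.93) and LHX9 (5.34). SOX, FOX, POU and T-box genes had peaks at 17 of 101 against 8.15 (adjusted permutation p = 0.0123), led by TBX20 (7.05-fold) and FOXJ2 (6.68), a call lost with the widened gene span (adjusted permutation p = 0.206). Cadherin and protocadherin genes had fewer, at 4 of 89 (PCDH10, PCDH17, PCDH9 and CDH2) against 11.9 (adjusted permutation p = 0.0216), and keratin and keratin-associated protein genes 0 of 149 against 7.32 (adjusted permutation p = 0.0056). Zinc finger genes of the ZNF, ZSCAN and ZKSCAN families counted 43 of 545 against 52.9 (adjusted permutation p = 0.257, or 0.0204 with the widened span). Ephrin and Eph receptor genes (5 of 23, adjusted permutation p = 0.314), proteasome genes (2 of 50, adjusted permutation p = 0.391) and DEAD and DEAH box helicase genes (9 of 54, adjusted permutation p = 0.261) did not pass. Cadherin and keratin genes lie partly in clusters, where neighbours are not independent. The same limit holds for homeobox genes, whose members with a peak include the neighbours DLX1 and DLX2 on chromosome 2. Adjustment was over these 8 families only and does not cover their choice after the peaks were seen.

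The 3 peaks of over 300-fold inside MECOM invite a check for extra DNA of the locus. Copy gain of the whole gene would raise fragments all along it. The 3 peaks held at least 1048 fragments and the other peaks inside the gene at most 28 (upper 95% bound 40.5), a ratio of 37.4. Because the 3 peaks were set apart by their height, a high ratio was given in advance. The low counts at the other peaks show only that fragments were not raised to the level of the 3 along the whole gene. Gain together with binding, and gain of a part of the gene, were not tested. DNA of the introduced MECOM construct may have been recovered, as the other peaks inside the gene reached no more than 7.40-fold. Neither the make-up of the construct nor exon positions were used here, so construct DNA and binding within MECOM cannot be told apart. The vector library was not analysed here.

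Peaks per gene were uneven along the genome, with 28.6 per 100 protein-coding genes on chromosome 6 and 26.9 on chromosome 13 against 9.32 on chromosome X. The number of genes bears on this ratio. Chromosome 13 held 91 peaks and 338 genes. Chromosome 19, with 149 peaks and 1451 genes, stood at 10.3, and chromosome 11, with 127 peaks and 1301 genes, at 9.76. Copy gain may contribute and would raise the background, provided the library behind it came from these cells, but on chromosome 6 from 25 to 30 Mb, with 52 peaks, the median background of 2.37 lay within the spread of windows (27.5% of 306 others were as low or lower), which neither favours nor excludes gain there. Across the genome, a first test found no detectable difference between the 27 windows of 5 Mb with 15 or more peaks and 280 others with at least 5 (mean log2 difference 0.066, permutation p = 0.534). After that null result, background was found to rise with peaks per protein-coding gene over these 307 windows (rho = 0.381, or 0.265 at equal gene number) and over all 546 windows with a gene and at least 1 peak (rho = 0.316, or 0.296 at equal gene number), each with permutation p = 1e-05, the smallest the resampling can give. Copy gain stays open on tests chosen after a null result, windows are not replicates, and no biological explanation was tested.

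The gathering of peaks at gene starts may reflect general recovery of active promoters in any precipitate. Ribosomal protein genes, taken as a class active in every cell, would then carry peaks more often than other genes. They had 0.910 times the expected number (adjusted permutation p = 1). That count took assigned peaks at any distance, among them those of RPL10L (21334 bp) and RPS3 (−15099 bp). With peaks across a start only, 2 genes were counted against 1.23 expected, a ratio of 1.63. At 5 genes against 5.49 expected, or 2 against 1.23 across a start, neither count excludes or favours the explanation. The vector library would bear on it. Since the library behind the background is not identified here, whether the vector library already served there cannot be told.

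At 24 peaks the background was 20 fragments or more, with enrichment from 1.45 to 4.82-fold and 55 to 497 fragments. They included peaks assigned to MIR6724-2 and MIR6724-4 on chromosome 21, RNU2-1 on chromosome 17 and TLE4 on chromosome 9. The others had no gene symbol. Many of these lay close together, on chromosome X from 115727329 to 115888009 and on chromosome 15 from 101752861 to 101764233.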
